A study of Drosophila melanogaster with 4 samples.

How the data were processed

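Salivary glands of wandering third-instar Drosophila melanogaster larvae were dissected, cross-linked and subjected to chromatin immunoprecipitation with a rabbit polyclonal antibody raised against full-length ORC2, per the labels' protocols. Libraries were made with the standard Illumina protocol with selection of 150 to 200 bp fragments and sequenced on a Genome Analyzer II. The series' design text gives 36 nt reads. The labels describe 4 samples. An ORC2 library from a first and one from a second chromatin extraction are labelled SuUR mutant, and these formed the only group with peak lists (replicates 1 and 2). The other entries are labelled wild type (Oregon-R), one as ORC2 ChIP DNA and one as input DNA. They were not analysed here, so no comparison of genotypes or with input was made. Each is named as the second channel of the same extraction as a mutant library, although sequencing has no channels, and the series' design text names the mutant strain alone. Whether these entries are separate libraries, or the control used in calling the peaks, is not stated in the sources used here. The labels of both lists and the design text name the mutant. The wild-type entries named for the same extractions leave some doubt, so the genotype is reported as labelled. Nothing in the labels says that the extractions came from separate animals or days.

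Peaks had been called with PeakSeq, a peak caller that compares a ChIP library with a control, per the file headers and the source column of the lists. Positions refer to FlyBase release 5.1, per the file headers. The aligner, the version and thresholds of the caller and the control library are not given in the sources used here. Each deposited list gives a start, an end and a score for every peak, and the authors' score carries no unit. Its scale is not given in the sources used here. The scores in the lists ranged from 1.13 upwards. They were used to describe, rank or filter peaks and to compare the 2 replicates at shared regions. They were also compared between arms, between shared and unshared peaks, and inside and outside the peak-free domains defined below. Scores of regions bordering those domains were compared with random draws. Replicate peaks were called per library: neighbouring peaks of a replicate list were never closer than 200 bp. The replicate lists held 63 and 84 peaks of 1 bp. The combined list had been made by the authors and was compared with the replicate lists to find how.

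The lists hold no read counts, so the depth of the libraries is unknown and no correction for depth was possible. All intervals on peak numbers and shares (95%, exact Poisson or exact binomial) cover counting error only and treat peaks as independent, which clustered peaks are not. Bootstrap intervals of medians came from 2000 resamplings of peaks. With 2 libraries of one group, no test between samples was made. The permutation tests ask whether positions coincide or cluster beyond random placement, or whether regions at domain borders score higher than random draws. They say nothing about variation between animals.

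Peaks were compared by overlap of at least 1 bp. For the chance level, one list was rotated 1000 times by a random distance within each arm or scaffold, which keeps widths and spacing (200 rotations per width class). The one-sided p was the number of rotations at or above the observed number plus 1, divided by the number of rotations plus 1. Arm lengths were taken as the span from position 1 to the end of the last peak in any list, which gave 120 Mb for the 6 main arms (2L, 2R, 3L, 3R, 4 and X). A region's score per replicate was the mean over its overlapping peaks of that replicate. Peak-free domains were stretches of at least 100 kb between neighbouring peaks of an arm, leaving out the chromosome ends. Their number and total length were compared with 1000 placements of the same peaks at uniform random positions without overlap. In an added test, runs of peaks within 10 kb of each other were placed as blocks at least 10 kb apart. Centromere-proximal stretches were the last 2 Mb of 2L, 3L and X and the first 2 Mb of 2R and 3R.

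Planned before the data were examined were the 1 bp overlap, the rotations, the uniform placements, the 100 kb minimum and the alternatives: reciprocal overlap of 50%, midpoints within 500 bp, peaks at or above the median score, equal list lengths, each replicate list alone, the union of the lists, and domain minima of 50 and 200 kb. The rule for named items, fixed at the same time, took the 10 highest-scoring combined regions and the 10 longest domains by position where no annotation of the same genome release could be used. The planned tests of peaks against transcription start sites (within 1 kb) and of 16 gene lists were not run, because the gene table at hand describes release 6 of the genome and positions were not converted between releases. The comparisons by arm end, by 100 kb window, by peak width and of score by arm were added after the data were seen.

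The scripts were tested on simulated lists. Where 8247 simulated peaks had a known set copied into a second list, 100% of the copied peaks were found, and the count of shared peaks (4943) equalled that of bedtools 2.31.1. Of 40 pairs of unrelated simulated lists, 0 gave a rotation p of 0.05 or less. Those lists were placed uniformly, so the check did not cover clustered peaks like the real ones. All 40 emptied stretches planted in a single simulated combined list were found, and the same list before emptying gave a uniform-placement p of 0.975. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.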

Results

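The data were lists of genomic regions bound by ORC2, a subunit of the origin recognition complex that marks potential start sites of DNA replication, in salivary glands of wandering third-instar larvae of Drosophila melanogaster. Cells of this gland replicate their DNA repeatedly without dividing and carry polytene chromosomes. Peak lists were analysed for 2 chromatin immunoprecipitation libraries labelled as SuUR mutant (replicates 1 and 2), together with a combined list for the series. SuUR (Suppressor of Underreplication) is known as a gene needed for the incomplete replication of certain chromosome regions in polytene cells. Entries labelled wild type, one as ORC2 ChIP DNA and one as input DNA, were not analysed here, so the genotypes were not compared. The labels leave unclear whether these entries are separate libraries. The lists themselves are labelled mutant, and their genotype is reported as labelled, with some doubt left by these entries. The design therefore left 3 questions: how far the replicates gave the same regions, how the regions were spread over the chromosome arms, and where long stretches held none. Read counts were not part of the lists, so the depth of the libraries is unknown, and no replicate standard deviation is given for values that rest on 2 libraries.

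ORC2 was called at 8247 regions in replicate 1 and at 10621 regions in replicate 2. In replicate 1, 7018 peaks (85.1%) overlapped a peak of replicate 2 by at least 1 bp, and in replicate 2, 6703 peaks (63.1%) overlapped a peak of replicate 1. Rotating one list along each arm gave 456 ± 23.7 (SD, 1000 rotations) shared peaks of replicate 1, so the observed number was 15.4 times the chance value. For replicate 2 the rotations gave 456 ± 24.9 and the observed number was 14.7 times as high. Both exceeded all 1000 rotations (one-sided permutation p = 0.001, the smallest p that they can give). Where at least 50% of each of the 2 peaks had to overlap, the shares were 55.1% of replicate 1 and 42.8% of replicate 2, against rotation means of 0.880% and 0.681%.

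Most peaks were shared on every large arm, though the shares differed between some arms. In replicate 1 the share was 86.3% on 2L (95% exact binomial interval 84.4 to 88.0), 87.5% on 2R (85.7 to 89.1), 84.3% on 3L (82.5 to 86.0), 89.0% on 3R (87.4 to 90.4) and 85.3% on X (83.4 to 87.1), so the interval of 3R lay above those of 3L and X. The small chromosome 4 had 51 of 64 replicate 1 peaks shared (79.7%, 67.8 to 88.7). On the heterochromatic scaffolds (2LHet, 2RHet, 3LHet, 3RHet, XHet) and on U, which holds sequence not placed on an arm, 86 of 230 replicate 1 peaks were shared (37.4%, 31.1 to 44.0). In replicate 2 the share was 66.7% on 2L (64.5 to 68.8), 64.5% on 2R (62.3 to 66.6), 65.9% on 3L (63.9 to 68.0), 64.7% on 3R (62.7 to 66.7) and 61.9% on X (59.7 to 64.1), so the interval of X lay below that of 2L. Together, the replicate 2 shares were 64.7% on the 6 main arms (63.7 to 65.6) and 23.4% on the other scaffolds (19.3 to 27.8). These intervals treat peaks as independent and cover counting error only.

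Wide regions were shared far more often than narrow ones. Among peaks over 800 bp, 98.9% of 661 in replicate 1 and 97.7% of 1002 in replicate 2 overlapped a peak of the other library. Among peaks narrower than the 36 nt read length, 40.7% of 668 in replicate 1 and 5.29% of 1154 in replicate 2 did so, where rotation gave 2.92% and 2.20%. The score of the peak caller also went with sharing, over a smaller range. In replicate 1 the share was 79.0% in the lowest score decile, 74.6% in the second, 85.5% in the fifth, 92.7% in the ninth and 87.3% in the highest. In replicate 2 the share rose from 48.2% in the lowest score decile to 67.9% in the fifth decile and was 64.7% in the highest decile. Shared peaks had a median score of 1.76 in replicate 1 (95% bootstrap interval 1.75 to 1.77), against 1.60 (1.57 to 1.62) for peaks without a partner. The medians in replicate 2 were 2.33 (2.31 to 2.35) and 2.17 (2.14 to 2.20).

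**Figure D1:**
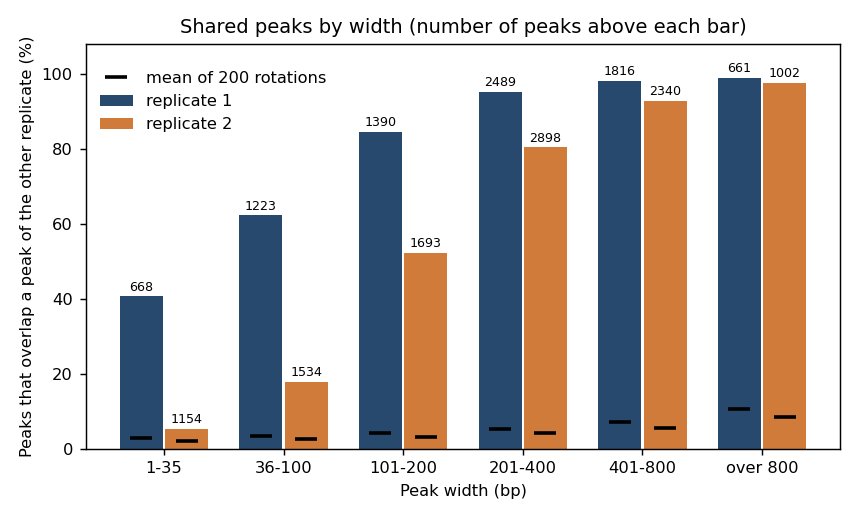
Share of peaks (%, y axis) that overlapped a peak of the other replicate by at least 1 bp, by peak width in bp (x axis), for replicate 1 (blue bars) and replicate 2 (orange bars), with the number of peaks above each bar and the mean of 200 rotations as a black dash. The share rose with width in both libraries, from 40.7% to 98.9% in replicate 1 and from 5.29% to 97.7% in replicate 2.

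The combined list held 6587 regions, and each was the union of overlapping peaks of both replicates. Its limits equalled the outer limits of the overlapping replicate peaks for 6587 of 6587 regions, and no merged region with peaks of both replicates was missing from it. A further 5147 merged regions rested on a single replicate, 1229 on replicate 1 and 3918 on replicate 2, and were absent from the combined list. The combined score equalled the mean of the replicate scores within 0.0001 for 6476 regions, including each of the 6095 regions made of 1 peak from each library. Combined regions had a median width of 438 bp and covered 3.60 Mb, whereas the median peak width was 258 bp in replicate 1 and 256 bp in replicate 2.

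Scores of the shared regions were correlated across regions, with Spearman's rho of 0.67 (95% bootstrap interval 0.66 to 0.68) and Pearson's r of 0.72 on log2 scores. Regions are not independent replicates, so no p is given. The score was higher in replicate 2 at 5965 of 6587 regions (90.6%), with a median ratio of replicate 2 to replicate 1 of 1.31. On U the order was the opposite: 27 of 34 regions did not score higher in replicate 2, and the median ratio was 0.613. The correlation was 0.68 on the main arms (0.67 to 0.69) and 0.20 on the other scaffolds (-0.02 to 0.40, 84 regions).

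**Figure D2:**
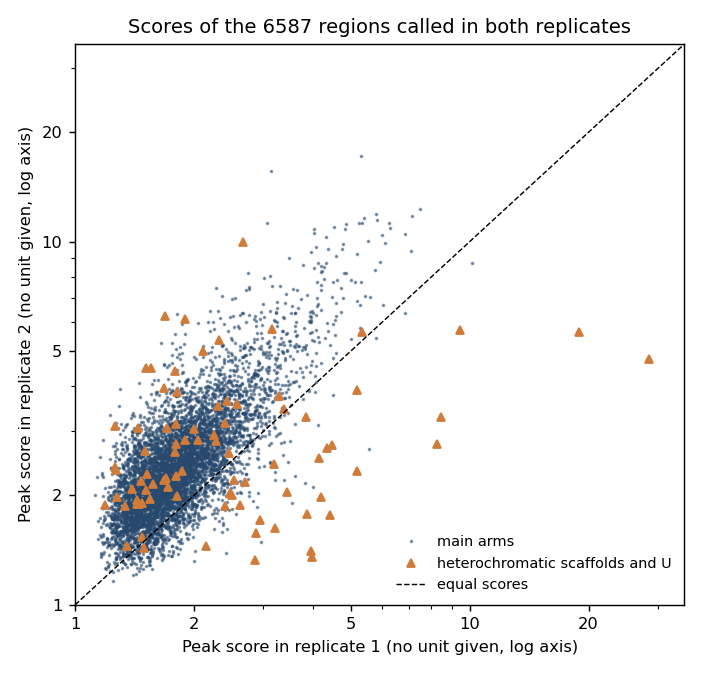
Score in replicate 1 (x axis) against score in replicate 2 (y axis) of the 6587 regions called in both, on log axes; the scores carry no stated unit. Blue points are regions on the main arms, orange triangles are regions on heterochromatic scaffolds and U, and the dashed line marks equal scores, above which 5965 regions lie.

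The 10 regions with the highest combined score lay on U, 2R, X, 2L and 3R, and each was narrower than the median region. All positions are in FlyBase release 5.1. The highest were ORC5381 at U 8148351 to 8148525 (combined score 16.6) and ORC5385 at U 9289212 to 9289380 (12.3), and both scored higher in replicate 1 (28.4 and 18.9) than in replicate 2 (4.75 and 5.62). On the arms the highest was ORC1921 at 2R 12687652 to 12687858, with a score of 5.31 in replicate 1 and 17.2 in replicate 2. ORC1173 at 2L 21397236 to 21397556 scored 10.2 in replicate 1 and 8.74 in replicate 2. The X chromosome held 4 of the 10. ORC5911 at X 9396305 to 9396736 scored 7.48 and 12.3 in replicates 1 and 2, and ORC5570 at X 3179378 to 3179679 scored 7.16 and 11.7. ORC5666 at X 5183771 to 5184030 scored 5.80 and 11.9. ORC6053 at X 11929335 to 11929507 differed most between the replicates among these 10 in relative terms, apart from ORC5381, with scores of 3.14 and 15.7. On 3R, ORC4516 at 12803763 to 12803912 scored 6.23 and 11.3, and ORC4168 at 5902461 to 5902705 scored 6.87 and 10.5. The genes at these positions were not identified, because no annotation of this genome release was used here.

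ORC2 regions of the combined list were spread over all main arms at 54.1 per Mb (95% exact Poisson interval 52.8 to 55.4), covering 2.94% of their length. The density was 52.3 per Mb on 2L (49.4 to 55.4), 58.1 on 2R (54.9 to 61.5), 55.2 on 3L (52.3 to 58.2), 52.9 on 3R (50.2 to 55.6) and 53.3 on X (50.3 to 56.4). X and the large autosome arms did not differ beyond counting error, with a density ratio of 0.979 (0.918 to 1.04). Chromosome 4 had 37.7 regions per Mb (27.9 to 49.8), or 0.692 times the density of the large autosome arms (0.511 to 0.916). The ratio for chromosome 4 was 0.735 (0.565 to 0.939) in replicate 1 and 0.818 (0.657 to 1.01) in replicate 2, so the interval of replicate 2 included equality. Among regions at or above the median score of the combined list, chromosome 4 had 30.0 per Mb. The large autosome arms then had 26.1 (2L), 28.8 (2R), 27.4 (3L) and 21.8 (3R), so the lower density of chromosome 4 was not seen there. The other scaffolds had 4.52 regions per Mb (3.60 to 5.59) over the stretches reached by any peak. The single replicate lists gave 66.7 peaks per Mb of main arm in replicate 1 and 85.0 in replicate 2. On the other scaffolds they gave 12.4 and 21.4, a smaller contrast with the main arms than in the combined list. The combined list keeps shared peaks alone, and 37.4% and 23.4% of the peaks on these scaffolds were shared. The lists hold no coverage, so sequence where no reads can be placed was not assessed.

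Scores were higher on X and on chromosome 4 than on the large autosome arms. The median combined score was 2.19 on X (95% bootstrap interval 2.14 to 2.22) and 2.47 on chromosome 4 (2.35 to 2.69), against 2.03 on the large autosome arms together (2.01 to 2.04). In replicate 1 the medians were 1.78 on X (1.75 to 1.81), 1.97 on chromosome 4 (1.83 to 2.10) and 1.72 on the large autosome arms (1.70 to 1.73). The interval of X in replicate 1 overlapped those of 2L (1.71 to 1.76) and 3L (1.72 to 1.77). In replicate 2 they were 2.43 on X (2.39 to 2.48), 2.62 on chromosome 4 (2.40 to 2.95) and 2.22 on the large autosome arms (2.20 to 2.24). Among regions scoring at or above the median of the combined list, the density on X was 1.23 times that on the large autosome arms (1.13 to 1.33). This ratio restates the higher scores on X.

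Density was lower in the 2 Mb next to the centromere than on the rest of the arm on 4 of the 5 large arms. The 2 Mb of 3L next to the centromere held 28 combined regions (95% exact Poisson interval 9.30 to 20.2 per Mb), against 58.8 per Mb on the rest of the arm. On 2R the proximal 2 Mb held 46 regions (16.8 to 30.7 per Mb), against 61.8 per Mb elsewhere. On 2L and on X they held 54 regions each (20.3 to 35.2 per Mb), against 54.8 and 55.9 per Mb elsewhere. On 3R the proximal 2 Mb were denser than the rest, with 144 regions (60.7 to 84.8 per Mb) against 51.4 per Mb. Both replicate lists gave the same direction on each of these 5 arms, with a smaller contrast than the combined list. On 3L the ratio of proximal density to the rest was 0.238 in the combined list, 0.361 in replicate 1 and 0.433 in replicate 2. On 2R the ratios were 0.372, 0.395 and 0.562. The 1 Mb bin with the most regions was 3L from 17 to 18 Mb, with 91, and the bin from 23 to 24 Mb of the same arm held 8. These intervals cover counting error and not the clustering of peaks. Sequence where no reads can be placed was not assessed, so it cannot be told apart from fewer bound regions near the centromere.

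ORC2 regions were clustered along the arms. Over 1200 windows of 100 kb, the variance of the number of regions was 3.43 times its mean, against at most 1.09 in 1000 uniform placements (one-sided permutation p = 0.001, the smallest they can give). The densest window, 3L 17900001 to 18000000, held 24 combined regions, 39 peaks of replicate 1 and 41 of replicate 2. It was followed by 3R 12000001 to 12100000 with 22 combined regions and 2R 9800001 to 9900000 with 21. The highest count in any window of the placements was 19. Windows without a region numbered 158, against a mean of 4.74 and at most 14 in the placements. Peak counts per window were correlated between the replicates across windows (Spearman's rho 0.94).

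**Figure D3:**
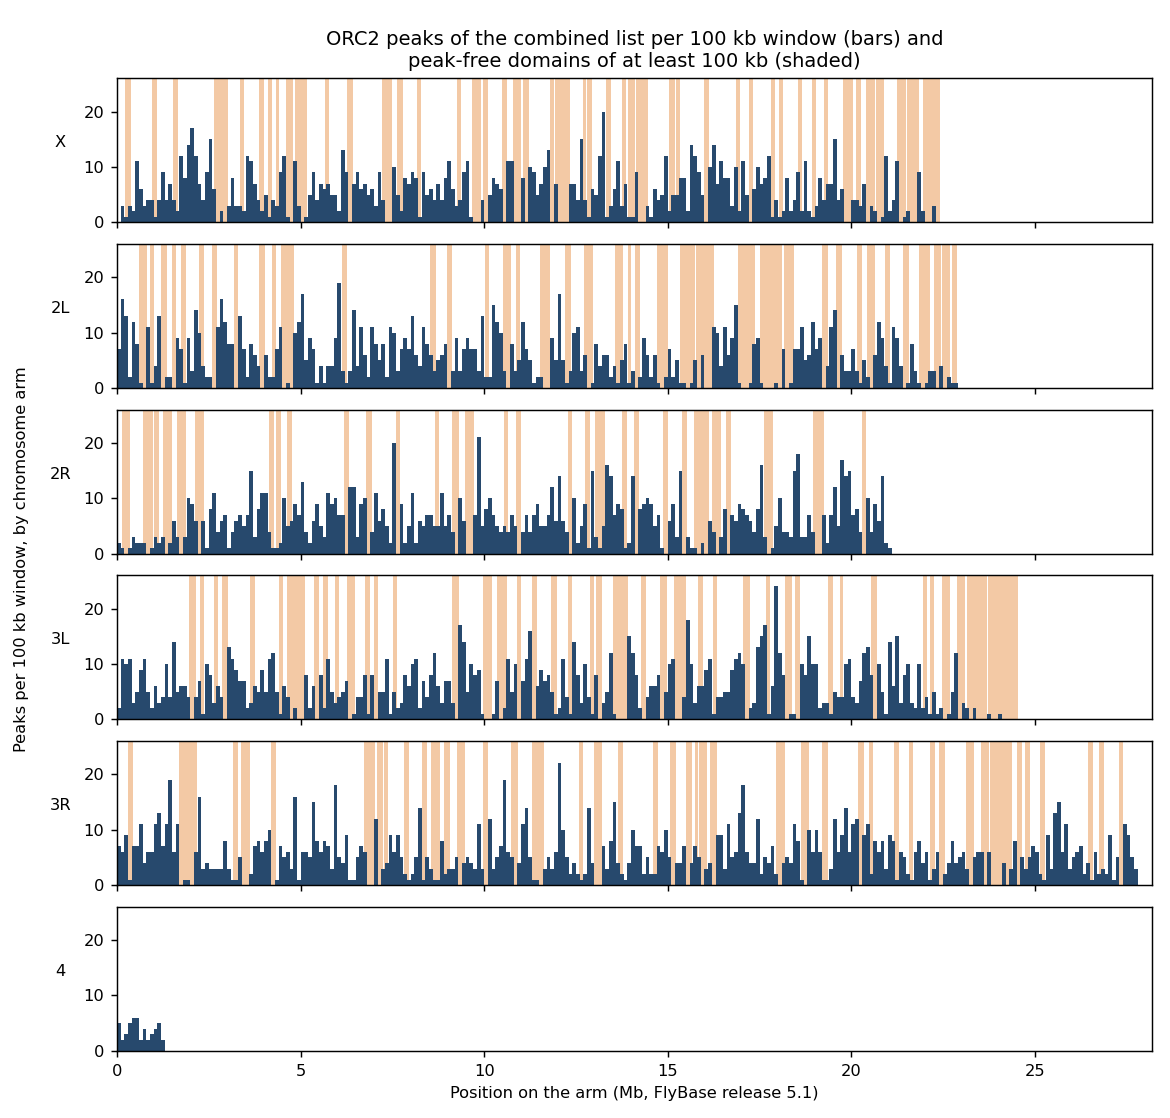
Number of combined ORC2 regions per 100 kb window (bars, y axis) along each main arm (x axis, position in Mb, FlyBase release 5.1), with peak-free domains of at least 100 kb shaded. Domains occur along all 5 large arms and crowd the right end of 3L, where the bin from 23 to 24 Mb holds 8 regions, and chromosome 4 has none.

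Long domains without any combined ORC2 region were found on all large arms. There were 224 stretches of at least 100 kb between neighbouring regions, with a median length of 145 kb and a total of 37.9 Mb, or 31.5% of the main arms. Uniform placement of the same regions gave 25.0 ± 4.71 (SD, 1000 placements) such stretches and at most 42, with at most 4.89 Mb in total (one-sided permutation p = 0.001 for number and length, the smallest they can give). Uniform placement ignores the clustering described above, so much of this excess restates it. Whole runs of neighbouring regions placed at random gave a mean of 153 and at most 184 stretches, with at most 24.4 Mb in total. By arm, domains took up 36.9% of X (50 domains), 35.2% of 2L (48), 33.9% of 3L (46), 28.1% of 3R (48) and 25.5% of 2R (32). Chromosome 4 had none, and its longest gap was 97397 bp.

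The domains were found in each library separately. Replicate 1 alone gave 212 domains (35.9 Mb) and replicate 2 alone gave 193 (28.99 Mb). They coincided over 28.1 Mb, which was 96.8% of the replicate 2 domain length and 78.2% of that of replicate 1, against a mean of 8.87 Mb and at most 14.3 Mb in 1000 rotations (one-sided permutation p = 0.001, the smallest they can give). The libraries were called in the same tissue and share their regions, so the coincidence is not independent of the overlap of peaks. Of the 224 combined domains, 173 held no peak of replicate 1, 71 no peak of replicate 2 and 66 no peak of either.

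The 10 longest domains lay on 3L (4), 2L (3), X (2) and 3R (1) and covered 3.88 Mb. The longest was 3L 24022013 to 24530186 (508174 bp), at the centromeric end of the arm, with 2 peaks of replicate 1 and 8 of replicate 2 that had no partner. Another proximal domain of 3L, 23332866 to 23707660 (374795 bp), held 2 and 1. The second longest was 2L 17501778 to 17962946 (461169 bp), with 2 peaks of replicate 1 and 4 of replicate 2. On the same arm, 2L 16910492 to 17260603 (350112 bp) and 2L 15914788 to 16251510 (336723 bp) held no peak of either library. In the middle of 3L, the domain from 13506822 to 13912742 (405921 bp) held 1 peak of replicate 1 and 2 of replicate 2, and that from 15156841 to 15491874 (335034 bp) held 1 of each. On 3R, the domain from 23783962 to 24151738 (367777 bp) held 1 and 3. On X, the domain from 11929508 to 12331218 (401711 bp) held no peak of replicate 1 and 2 of replicate 2. It began directly beside ORC6053 and ended beside ORC6054, with combined scores of 9.40 and 6.38. The X domain from 21504153 to 21846357 (342205 bp) began beside ORC6566, with a combined score of 8.30, ended beside ORC6567, with 1.62, and held 2 peaks of replicate 1 and 1 of replicate 2.

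**Figure D4:**
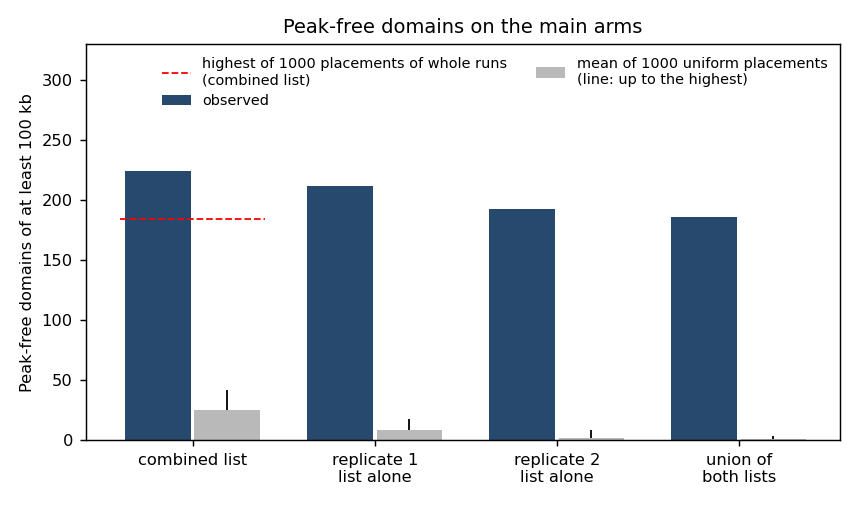
Number of peak-free domains of at least 100 kb on the main arms (y axis) in the combined list, in each replicate list alone and in the union of both (blue bars), beside the mean of 1000 uniform placements of the same peaks (grey bars, with a line up to the highest). The 4 lists gave 224, 212, 193 and 186 domains, and the dashed red line marks the highest number, 184, in 1000 placements of whole runs of neighbouring combined regions.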

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

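For peaks called in a single library, the tests of random positions and of median scores were set before their results were seen, and the comparisons of score deciles and of width were chosen after. Scores far beyond the rest appeared in data that the comparisons on the main arms do not use: 12 peaks of the replicate lists on heterochromatic scaffolds and U scored above 20, while no peak on the main arms did (highest 17.2). The highest were Rep2_ORC8562 at U 2524275 to 2524303 (score 2310, 29 bp), Rep1_ORC6749 at U 9598739 to 9598775 (619, 37 bp) and Rep1_ORC6750 at U 9692920 to 9692998 (488, 79 bp). They fell 6 in each replicate, 11 of the 12 had no overlapping peak in the other library, and their median width was 33 bp against 122 bp for the 616 other peaks on these scaffolds.

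Peaks called in a single library made up 1229 of the replicate 1 list and 3918 of the replicate 2 list. Random positions are argued against for these peaks as a set: 59.4% of them lay within 2 kb of a peak of the other library, against 20.3% on average in 1000 rotations (one-sided permutation p = 0.001, the smallest they can give). The share was 73.9% in replicate 1 and 54.8% in replicate 2, against 22.7% and 19.6%. Peaks farther away may still be random calls. The rotations also do not keep peaks out of sequence where no reads can be placed. A score near the threshold stays open, since unshared peaks had lower median scores in both libraries (1.60 against 1.76 in replicate 1 and 2.17 against 2.33 in replicate 2), although 64.7% of the highest score decile of replicate 2 and 87.3% of that of replicate 1 were shared. Narrow calls, whatever their score, stay open too: the shared percentage rose over every width class in both libraries, from 5.29% below the read length in replicate 2 and 40.7% in replicate 1. Whether narrow calls lie near the threshold cannot be told from the scores, as the threshold and the scale of the score are not given. Width and score were nearly unrelated across peaks (Spearman's rho 0.0083 in replicate 1 and 0.058 in replicate 2). Calls below the read length had median scores of 1.72 and 2.13, against 1.76 and 2.34 for those over 800 bp. No second group with peak lists was analysed, so no biological explanation was tested.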

How the results depend on the processing

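All settings named here were planned except those said to be added after seeing the data. The overlap of the replicates stayed beyond all rotations or placements under every setting run: from 55.1% (reciprocal 50% overlap) to 88.3% (peaks narrower than a read left out, added) of replicate 1, and from 42.8% to 67.8% of replicate 2. Keeping peaks at or above the median score of each list left 2663 combined regions with partners in both replicates, lowered the correlation of scores to 0.54, gave 26.9 regions per Mb of main arm and raised the density ratio of X to the large autosome arms from 0.979 to 1.23. The number and the density follow from the removal of peaks. The correlation then covered 2812 pairs within a narrower range of scores, so its fall cannot be read as poorer agreement. The higher ratio restates the higher scores on X (median 2.19 against 2.03). Counting reciprocal overlaps alone raised the correlation of scores to 0.72, and the cause was not tested. With a single replicate list, density ranged from 66.7 to 85.0 peaks per Mb, as the combined list leaves out unshared peaks and merges overlapping ones. Peak-free domains numbered 583 (62.4 Mb) at a minimum of 50 kb and 55 (14.8 Mb) at 200 kb, by construction, and 193 to 212 (28.99 to 35.9 Mb) in single replicate lists. Among regions at or above the median score they numbered 302 (53.3 Mb), against a mean of 213 and at most 242 in the placements, a smaller excess than the 224 against 25.0 of the full list. They numbered 186 (28.0 Mb) in the union of the lists and 195 (31.7 Mb) without the 2 Mb next to the centromeres (added). Each of these exceeded the highest number in its own 1000 uniform placements. Whole runs were placed for the full combined list alone. Tests against transcription starts and gene lists were not run. No paired analysis was possible because 1 group alone has peak lists. Depth, and so the smallest detectable peak, is unknown.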

Other observations

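The tests of domains below were set before their results were seen, except the count of domains empty in both libraries, the count by segments, the density away from peaks of the other library and the scores of bordering peaks. Beyond the 3 densest windows described above, ORC2 regions were crowded at 2R 7500001 to 7600000 and X 13200001 to 13300000, with 20 combined regions each. A further group at 2L 6000001 to 6100000, 3R 1400001 to 1500000 and 3R 10500001 to 10600000 held 19 each, which equals the highest count that any uniform placement reached. The last of these had 21 peaks in replicate 1 and 31 in replicate 2, and the X window had 23 and 22.

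The 224 long peak-free domains are more than chance spacing gives, since uniform placement gave at most 42. Short-range runs of peaks account for part of the number: placing whole runs at random gave a mean of 153 and at most 184 domains, and at most 24.4 Mb against 37.9 Mb observed. Peaks called in a single library were also sparse inside the domains, with a density 0.216 times that outside (425 inside against a mean of 1483 in 1000 rotations). Part of this follows from choosing domains without shared regions, as 59.4% of all such peaks lay within 2 kb of a peak of the other library. For those over 2 kb away the density was 0.430 times that outside, with no rotation interval. These values argue against even loss of peaks to depth or threshold as the sole cause. Sequence where no reads can be placed would leave the same sparsity. Sequence where no reads can be placed stays open, although 158 domains (70.5%) held a peak of a single library and the criterion set before would have ruled it out on that count. That criterion was too weak, because these peaks had median widths of 59 bp in replicate 1 and 91 bp in replicate 2 and each shows reads at its own spot only. By a stricter count added after seeing this, peaks lay in at least 50% of the 20 kb segments in 8 domains. For the rest, and for the 66 domains without a peak of either library, such sequence cannot be told apart from a lack of binding, as the lists hold no coverage. The SuUR genotype stays open as untested because no wild-type list was analysed here, and the genotype itself rests on the labels alone.

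Peaks that border the domains may be stronger than others, a hypothesis drawn from ORC6053 and ORC6566 beside 2 of the longest domains. Of the 20 borders of the 10 longest domains, 9 scored below the median of the regions that border no domain. The 433 bordering regions had a median combined score of 2.23 (95% bootstrap interval 2.15 to 2.30) against 2.04 for the other 6070 on the main arms, and none of 100000 random draws of as many regions per arm reached it (one-sided permutation p = 1e-05, the smallest they can give). ORC6053 and ORC6566 are among the 433, so this p is no independent support for a hypothesis drawn from them. The draws matched the arm and not the spacing of regions. They cannot tell regions beside a domain from isolated regions in general. The direction was the same in replicate 1 (1.89 against 1.76) and replicate 2 (2.53 against 2.33). A candidate explanation is a low control signal across the domains, which would raise every score there. Peaks of replicate 2 alone had a median score of 2.36 inside the domains (2.26 to 2.48) against 2.12 outside (2.09 to 2.15). In replicate 1 the medians went the same way (1.65 inside, 81 peaks, against 1.54 outside). Their intervals overlapped (1.55 to 1.73 against 1.52 to 1.57), so this explanation stays open.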
